A study of Homo sapiens with 4 samples.

How the data were processed

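The series holds 4 RNA libraries of MDA-MB-231 cells grown in L15 medium with serum. For the pulldown, cells were lysed and RNA was immunoprecipitated with an anti-PABPC1 antibody on magnetic beads, and the input library stands for the lysate. The protocol also mentions IgG, but no IgG library was analysed here. For the knockdown, the labels name both an siRNA and a Smart Silencer against LINC00882, and the negative control is called si_NC here. Groups were taken from the sample labels. Whether the libraries were selected for poly(A) RNA or depleted of ribosomal RNA is not given in the sources used here.

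Per the file headers, the authors deposited 1 FPKM value per gene and library (fragments per kilobase of transcript, scaled to the mapped fragments of the library). The submitters' processing notes name FastQC 0.11.7, cutadapt 1.17, HISAT2 2.1.0, StringTie 1.3.3 and the genome build GRCh37, without role or order. The annotation version, the filters and the read depth are not given in the sources used here. The tables hold 11712 genes for input and the pulldown and 11695 for both transfected libraries, with 11288 genes in all 4. Every gene of the first pair had at least 0.5 FPKM in 1 of its libraries, while 357 genes of the second pair were below that in both and 22 were listed at 0 in both, so the tables differ in how genes were chosen. Almost all genes are protein-coding, and LINC00882 was not analysed here. FPKM are not counts, the depth is unknown, and what a single fragment is worth depends on transcript length, so no interval or detection limit was computed.

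Each library was compared within its pair as the log2 ratio of FPKM plus a pseudocount of 1, among genes with at least 1 FPKM in either library. Every log2 ratio is on this scale, which understates the change of low genes, and no fold is given against a value listed at 0. Values were used as deposited. With 1 library per group no p-value was computed, and genes with a log2 ratio of at least 1 in either direction (2-fold) were counted. The summed FPKM was 338894 in input, 197844 in the pulldown, 209725 in si_NC and 216346 in si_LINC00882. The number of genes listed at 0 was 87, 10, 50 and 53 in the same order.

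Gene lists were written before the data were examined, and each list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile was given only for lists of at least 5 measured members. Named genes follow a rule also fixed before the data were examined. They are PABPC1, the 12 highest and 12 lowest ratios per comparison among genes of at least 5 FPKM in either library without clone names, small RNAs and pseudogenes, up to 4 members of each list described (the same minimum, largest absolute ratios), and the 10 genes with the largest smaller ratio of both comparisons. A few genes that the rule names are not reported here, and no others take their place. The expected overlap of independent lists is the product of both counts over the number of genes compared in both pairs. Random overlaps were drawn with matched expression.

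Gene symbols were matched to RefSeq genes of the GRCh38.p14 assembly, which is not the build of the deposited values, so it served only for names, gene types and for which genes overlap, and no coordinates are printed. Of the symbols, 11548 matched for the first pair and 11464 for the second. The alternatives were pseudocounts of 0.1 and 5, no minimum and a minimum of 5 FPKM, centring on the median ratio, rescaling without mitochondrial genes, protein-coding genes only, size rules of 1.5-fold and 3-fold, and the control library of the other pair. Leaving out genes that overlap another listed gene and clone names was added after seeing the data.

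The steps were tested on simulated libraries built from the control values with a noise SD of 0.15 on the log2 scale. Of 100 genes of at least 5 FPKM changed 4-fold all were recovered in both designs. Of those changed 3-fold, 99% were recovered among 10350 genes in the knockdown design and 97% among 9555 genes in the pulldown design, with 0 unchanged genes called. That 0 follows from the chosen noise and gives no rate of false calls for the real libraries. Input and si_NC, for example, differed by 2-fold or more at 25.1% of genes. Of 100 simulated lists of 30 genes per design, 2% and 4% of unshifted lists, and all lists shifted by 0.5, fell outside the central 95%. These lists were drawn at random, so their genes do not vary together as members of a real list can. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.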

Results

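Transcript levels were compared in 4 libraries of MDA-MB-231, a human triple-negative breast cancer cell line. One pair compared cells transfected with a silencer against the long non-coding RNA LINC00882 (si_LINC00882) with cells given a negative control silencer (si_NC). The other pair compared RNA recovered with an antibody against PABPC1, the main cytoplasmic poly(A)-binding protein, with the input RNA. Each group was 1 library, so there were no replicates, no test was possible, and every difference below describes these libraries only. LINC00882 itself was not analysed here, so the extent of its knockdown was not checked. PABPC1 mRNA stood at 173 FPKM in the si_NC library and 158 in the si_LINC00882 library, at 412 in the input library and at 255 in the pulldown library.

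AHNAK, which encodes a very large scaffold protein under the plasma membrane, was the gene most strongly lower in the si_LINC00882 library among the named genes, at 3.43 FPKM against 111 in the si_NC library (log2 ratio -4.66). DAG1, the dystroglycan receptor that links cells to the extracellular matrix, stood at 2.36 against 16.5 FPKM (-2.38). SPIN1, a reader of methylated histone H3, stood at 3.38 against 19.8 FPKM (-2.25). RRM2, the small subunit of ribonucleotide reductase, stood at 18.1 against 57.4 FPKM (-1.61). In the other direction, MSRB3, a methionine sulfoxide reductase, stood at 11.1 FPKM against 1.49 (2.27), and the beta-tubulin gene TUBB2B at 10.7 against 1.54 (2.21). The input library, of other treatment and handling, held AHNAK at 6.38 FPKM, SPIN1 at 0.961, RRM2 at 4.70 and MSRB3 at 12.6. These levels lay nearer to si_LINC00882 than to si_NC, and SPIN1 and RRM2 were higher in si_LINC00882 than in input. DAG1 in input (7.96) lay between si_LINC00882 and si_NC, and TUBB2B (0.390) was nearer to si_NC.

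Of 10478 genes compared between these libraries, 90 were at or past 2-fold higher and 121 at or past 2-fold lower in the si_LINC00882 library, 2.01% in all. Across genes, which are not independent replicates, the log2 levels of both libraries correlated with Pearson's r of 0.978. Among the other genes with the lowest ratios were NUP50, a nuclear pore component (14.7 to 2.75 FPKM from si_NC to si_LINC00882, -2.07), and PWP2, a ribosome assembly factor (5.71 to 0.560, -2.10). The ubiquitin ligase TRIM32 stood at 5.99 in si_NC and 1.00 in si_LINC00882 (-1.80), and the F-box gene FBXO34, whose span overlaps ATG14, at 12.6 and 1.81 (-2.28). Among those with the highest ratios were the G protein subunit GNA12 (4.32 and 18.1, 1.84), the taurine transporter SLC6A6 (4.87 and 19.99, 1.84) and the surface glycoprotein MPZL1 (5.46 and 21.7, 1.81). TUBB3 stood at 1.64 and 9.77 FPKM (2.03) and C19orf68 at 1.05 and 6.49 (1.87). The spliceosome and snoRNP protein gene SNU13 (9.15 and 32.5, 1.73) and the actin-associated PPP1R18 (8.11 and 26.6, 1.60) each overlap another listed gene. Tubulin genes are close paralogs, so the assignment of fragments among them is uncertain. In input, TUBB3 (9.83 FPKM), GNA12 (13.1), MPZL1 (21.4), PPP1R18 (24.9) and FBXO34 (0.0861) stood nearer to si_LINC00882. SLC6A6 (7.79), SNU13 (12.4), NUP50 (12.2) and PWP2 (3.23) stood nearer to si_NC, while C19orf68 (2.99) and TRIM32 (2.80) lay between.

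Several of the largest ratios belonged to genes that share a span with another listed gene, 6 of the 12 lowest and 5 of the 12 highest. ZBED6, which lies within the gene ZC3H11A, stood at 16.9 FPKM in si_NC and 1.46 in si_LINC00882 (-2.86), while ZC3H11A stood at 1.80 and 15.3 (2.54). The readthrough gene FAM47E-STBD1 was at 5.95 in si_NC and listed at 0 in si_LINC00882, while STBD1, a glycogen-binding protein gene, stood at 1.64 and 12.1 (2.31). PTGES3L-AARSD1 was at 12.5 and listed at 0, while AARSD1 stood at 2.64 and 9.38 (1.51). C7orf55-LUC7L2 was at 11.5 and listed at 0, and C15orf38-AP3S2 at 6.25 and 0.590 (-2.19). How fragments were divided between such genes is uncertain.

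Of 27 gene lists with enough measured members, 4 had a median log2 ratio above the central 95% of 10000 random lists matched on expression and 2 a median below it, as a description of this pair of libraries. The 13 mitochondrially encoded mRNAs had a median of 0.29 (percentile 99.96), with MT-ND5 at 879 FPKM in si_NC and 1264 in si_LINC00882 (0.52) and MT-CYB at 1343 and 1828 (0.44). None of them reached 2-fold, and these mRNAs made up 16.3% of the summed FPKM in si_NC and 19.3% in si_LINC00882. The 19 measured replication-dependent histone genes had a median of 0.21 (percentile 99.65), with HIST2H2AA4 at 3.83 and 5.50 FPKM (0.43). HIST1H2BK stood at 52.6 and 45.4 (-0.21) and HIST1H1C at 35.7 and 33.1 (-0.11). Over the 31 histone genes listed in all 4 libraries, the median level was 1.11 FPKM in si_NC and 0.976 in si_LINC00882. Histone genes are paralogs of near-identical sequence, and HIST2H2AA4 overlaps another listed histone gene. The 24 apoptosis genes had a median of 0.13 (percentile 99.13). Among them BAD, which promotes apoptosis and overlaps GPR137, stood at 19.4 and 28.4 FPKM (0.53). CYCS stood at 56.9 and 73.0 (0.35), and the inhibitor of apoptosis BIRC3 at 10.8 and 15.4 (0.48). None was at 2-fold higher and 1 was lower, XIAP, another inhibitor of apoptosis (4.49 and 0.496, -1.87), which was named after its values were seen. The 336 ZNF zinc finger genes had a median of 0.07 (percentile 100), and 5 were at 2-fold higher and 2 lower, with ZNF473 (1.33) and ZNF664 (1.06) above and ZNF672 (-1.73) and ZNF182 (-1.43) below.

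The 28 interferon-stimulated genes had a median of -0.15 (percentile 0.29), and none reached 2-fold. EIF2AK2, the kinase PKR that senses double-stranded RNA, stood at 12.2 FPKM in si_NC and 8.37 in si_LINC00882 (-0.50), and overlaps GPATCH11. DDX58, the viral RNA sensor RIG-I, stood at 8.30 and 6.51 (-0.31). The 79 cytosolic ribosomal protein genes had a median of -0.05 (percentile 1.63), although the members with the largest ratios lay above 0, such as RPL29 (82.8 and 121, 0.54) and RPS15 (69.6 and 99.3, 0.51). With input in place of si_NC as the control, 4 of these 6 list medians changed sign. They were mitochondrial mRNAs (-1.85, percentile 0), histones (-0.34, percentile 0.02), interferon-stimulated genes (0.079, percentile 5.5) and apoptosis (-0.0032). The median of all genes was 0.28 in that comparison, so the interferon-stimulated genes stayed on the low side, within the random lists. Ribosomal proteins (-0.48, percentile 3.28) and ZNF genes (0.47, percentile 81.82) kept their sign but fell within the random lists.

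The other lists lay within the range of the random lists. Of the 38 DNA replication genes (median -0.08, percentile 4.30) only RRM2 reached 2-fold, and MCM6, a subunit of the replicative helicase, stood at 41.4 and 31.8 FPKM (-0.37). Of the 34 mitosis genes (median -0.02, percentile 32.04) only the transcription factor gene FOXM1, which overlaps ITFG2 and RHNO1, reached 2-fold (9.91 and 25.1, 1.26), and the kinase gene AURKA stood at 48.0 and 78.6 (0.70). Of the 22 NF-kB target and cytokine genes (median -0.01, percentile 45.35) only IL11 did (16.0 and 5.23, -1.45), while IL6 stood at 24.3 and 16.0 (-0.57). Of the 33 genes for poly(A)-binding proteins and deadenylation (median -0.02, percentile 33.66) only the deadenylase CNOT6L did (5.22 and 1.72, -1.19). Among the 5 measured neighbours of LINC00882 on its chromosome (median 0.01, percentile 55.49), the adhesion molecule ALCAM stood at 68.5 and 42.9 (-0.66), and CD47 (-0.13), IFT57 (0.13) and BBX (0.01) stood close to equal levels.

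**Figure D1:**
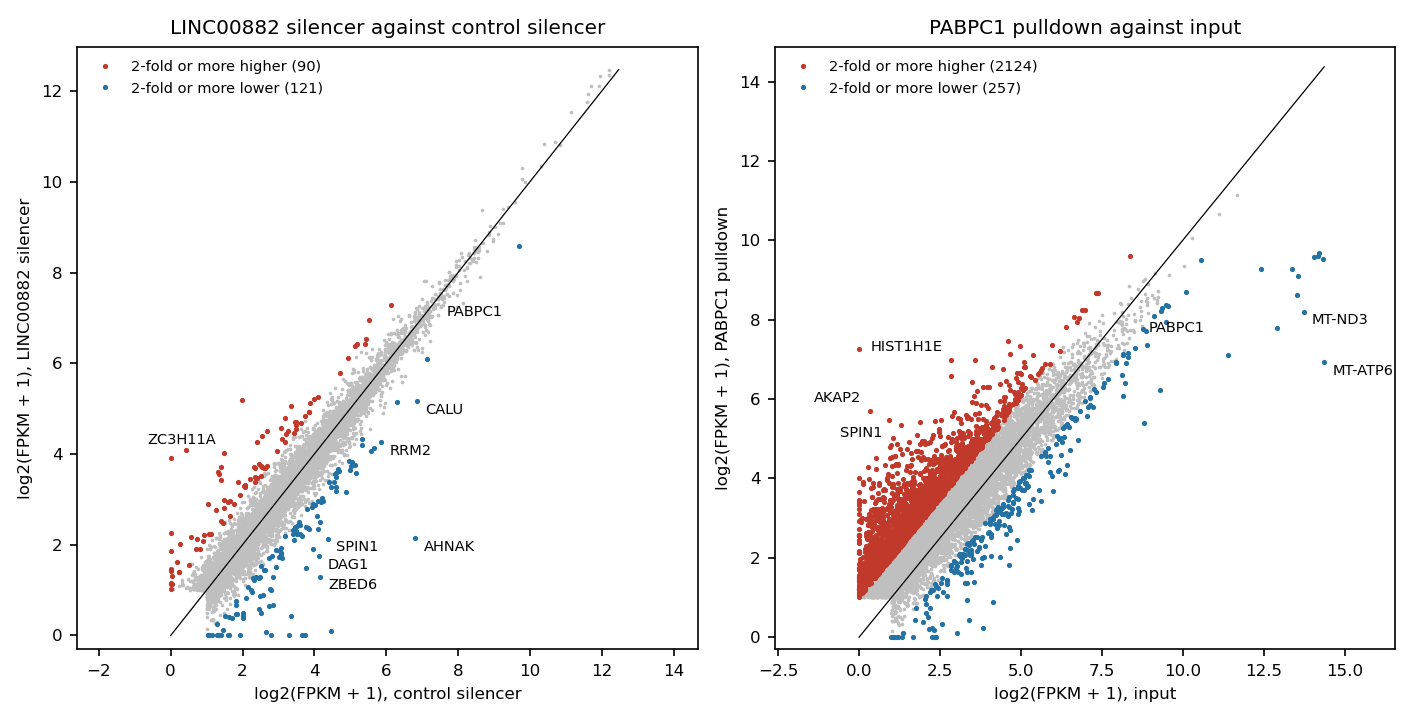
Levels of each compared gene, as log2(FPKM + 1), in the control library (horizontal) and in the other library (vertical) of each pair, with 1 point per gene, the diagonal marking equal levels and colours marking genes at or past 2-fold. The si_LINC00882 and si_NC libraries differ at 90 and 121 genes, whereas the PABPC1 pulldown lies above input at 2124 genes and below it at 257, with the mitochondrially encoded mRNAs far below.

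Mitochondrially encoded mRNAs were far lower, and replication-dependent histone mRNAs far higher, in the PABPC1 pulldown library than in input. All 13 mitochondrial mRNAs were past 2-fold lower (median log2 ratio -4.53, percentile 0), from 21171 FPKM in input to 121 in the pulldown for MT-ATP6, an ATP synthase subunit (-7.44), and from 12025 to 552 for MT-ND1 (-4.44). Of the 45 measured replication-dependent histone genes, whose mRNAs mostly end in a stem-loop in place of a poly(A) tail, 41 were at 2-fold higher and none lower (median 2.29, percentile 100). HIST1H1E stood at 6.17 FPKM in input and 126 in the pulldown (4.15), HIST1H2AH at 0.913 and 43.1 (4.53), HIST1H3C at 1.24 and 28.2 (3.70) and HIST1H2AI at 0.243 and 14.8 (3.67). Histone genes under 1 FPKM in input, such as HIST1H2AH and HIST1H2AI, were measured only through their pulldown level. Such genes could not be called 2-fold lower. Cytosolic ribosomal protein mRNAs were lower, with 17 of 79 at 2-fold lower and none higher (median -0.68, percentile 0), although only 2 were at 2-fold lower over si_NC (median -0.22).

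In this pair 2124 of 10856 genes were at or past 2-fold higher and 257 at or past 2-fold lower in the pulldown. The median log2 ratio of all genes was 0.47, so most genes lay somewhat above input, and with the pair centred on its median 943 genes were higher and 708 lower. Mitochondrially encoded mRNAs took 47.3% of the summed FPKM in input and 3.08% in the pulldown. Relative to the median of all genes, the list medians were 1.82 for replication-dependent histones, -4.99 for mitochondrially encoded mRNAs and -1.15 for ribosomal proteins. Pearson's r across genes was 0.903.

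All of the 12 lowest ratios belonged to mitochondrial mRNAs, the others being MT-ND3 (-5.54), MT-CYB (-5.13), MT-ND2 (-4.91), MT-CO3 (-4.80), MT-ATP8 (-4.56), MT-CO2 (-4.53), MT-ND4 (-4.47), MT-ND5 (-4.29), MT-CO1 (-4.08) and MT-ND6 (-3.39). Of the ribosomal proteins, RPS29 stood at 48.7 in input and 9.70 in the pulldown (-2.22), RPS3A at 286 and 66.9 (-2.08), RPL39 at 298 and 83.6 (-1.82) and RPS21 at 709 and 245 (-1.53). The 43 nuclear-encoded oxidative phosphorylation genes had a median of -0.23 (percentile 0.71), with 1 at 2-fold lower, the complex I subunit NDUFB9 (19.4 and 7.92, -1.19). The 8 histone variant genes with polyadenylated mRNAs lay within the range of random lists (median 0.40, percentile 90.13, and -0.06 with the pair centred), but above it over si_NC (0.61, percentile 98.46). Among them the linker histone H1F0 stood at 106 and 244 (1.20) and H3F3A at 103 and 44.4 (-1.19).

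**Figure D2:**
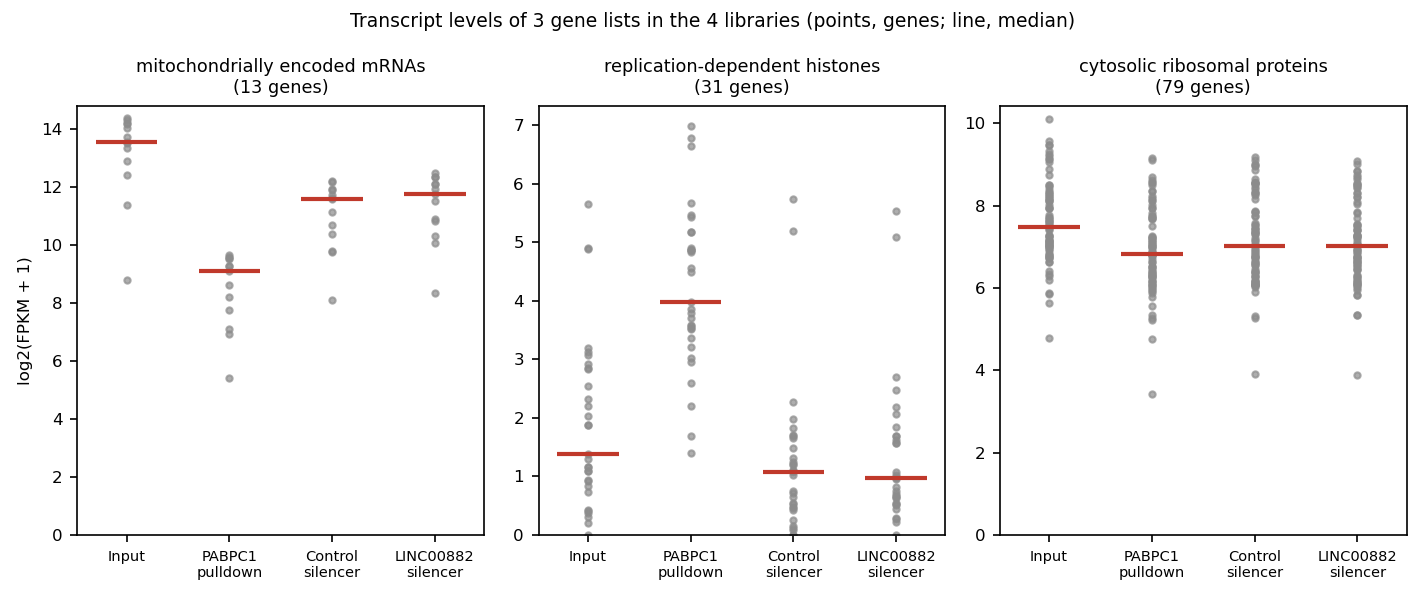
Levels of 3 gene lists, as log2(FPKM + 1), in the 4 libraries, with 1 point per gene listed in all 4 and a line at the median of each library. The median of the 13 mitochondrially encoded mRNAs is 12025 FPKM in input and 552 in the pulldown, and that of 31 replication-dependent histones is 1.60 in input, 14.8 in the pulldown and 1.11 in si_NC.

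Genes with the highest ratios in the pulldown included DPY19L1, a C-mannosyltransferase (0.424 FPKM in input and 21.7 in the pulldown, 3.996), and SPIN1 (0.961 and 27.7, 3.87). The readthrough genes BLOC1S5-TXNDC5 and SENP3-EIF4A1 were listed at 0 in input and stood at 152 and 15.0 in the pulldown. AKAP2 (0.259 and 51.3, 5.38), the poliovirus receptor PVR (1.44 and 39.9, 4.06), ZC3H11A (0.201 and 18.5, 4.02), the translocon subunit SEC61A1 (1.09 and 31.6, 3.96), RELL1 (0.923 and 26.7, 3.85) and FBXO34 (0.0861 and 14.1, 3.80) each overlap another listed gene. In all, 8 of the 12 highest share a span with another listed gene, so their values are uncertain.

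The lists of secreted and matrix, mesenchymal, cholesterol, glycolysis and hypoxia, and unfolded protein response genes also lay above the random lists. Of 33 secreted and extracellular matrix genes 17 were at 2-fold higher (median 1.01, percentile 100), among them the collagen COL6A1 (0.679 and 6.26 FPKM, 2.11) and prosaposin PSAP (33.3 and 122, 1.84). Of 24 mesenchymal and invasion genes, some on both lists, 12 were higher and 1 lower (median 0.91, percentile 100). They included the membrane protease MMP14 (10.7 and 66.8, 2.53), caveolin CAV1 (30.3 and 160, 2.37), the urokinase PLAU, which overlaps C10orf55 (40.3 and 138, 1.75), and the integrin ITGA5 (7.73 and 22.8, 1.45). Of 25 cholesterol synthesis and uptake genes 12 were higher (median 0.96, percentile 99.99), with INSIG1 at 16.2 and 111 (2.70) and the regulator SREBF2 at 6.42 and 19.98 (1.499). Of 34 glycolysis and hypoxia genes 11 were higher (median 0.79, percentile 99.99), with NDRG1 at 13.1 and 43.8 (1.67), P4HA2 at 1.07 and 5.04 (1.55), PKM at 21.8 and 64.8 (1.53) and ALDOC at 2.64 and 9.20 (1.49). Of 29 genes of the unfolded protein and ATF4 responses 7 were higher (median 0.70, percentile 99.72), with SLC7A5 at 34.1 and 110 (1.66), DDIT4 at 24.4 and 74.1 (1.57), the ER chaperone CALR at 160 and 409 (1.35) and SLC7A1 at 15.6 and 36.0 (1.16). In si_NC, MMP14 (69.5 FPKM), COL6A1 (12.7), PSAP (144), P4HA2 (7.48) and PKM (125) stood above their pulldown levels. The other genes named from these lists stood below theirs. Of the 333 ZNF genes 52 were at 2-fold higher, and their median of 0.51 lay below the random lists (percentile 0.70), a position it lost with the pair centred, without a minimum level and with a pseudocount of 5.

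The 33 genes for poly(A)-binding proteins and deadenylation lay within the range of random lists (median 0.35, percentile 42.32, and -0.15 with the pair centred). Of these, 4 were at 2-fold higher, namely the scaffold EIF4G1 that binds PABPC1 (12.7 and 56.4 FPKM, 2.07) and the deadenylase complex genes CNOT10 (1.81 and 5.49, 1.21), CNOT6 (8.31 and 20.2, 1.19) and CNOT3 (4.004 and 9.97, 1.13). Over si_NC only 2 members of that list were at 2-fold higher, and EIF4G1 (-0.76) and CNOT10 (-0.27) were lower in the pulldown. Against the si_NC library, which had another treatment and is another table, among the lists outside the random lists, the medians of the secreted, glycolysis and oxidative phosphorylation lists change sign, and those of the mesenchymal and unfolded protein lists fall within the random lists.

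**Figure D3:**
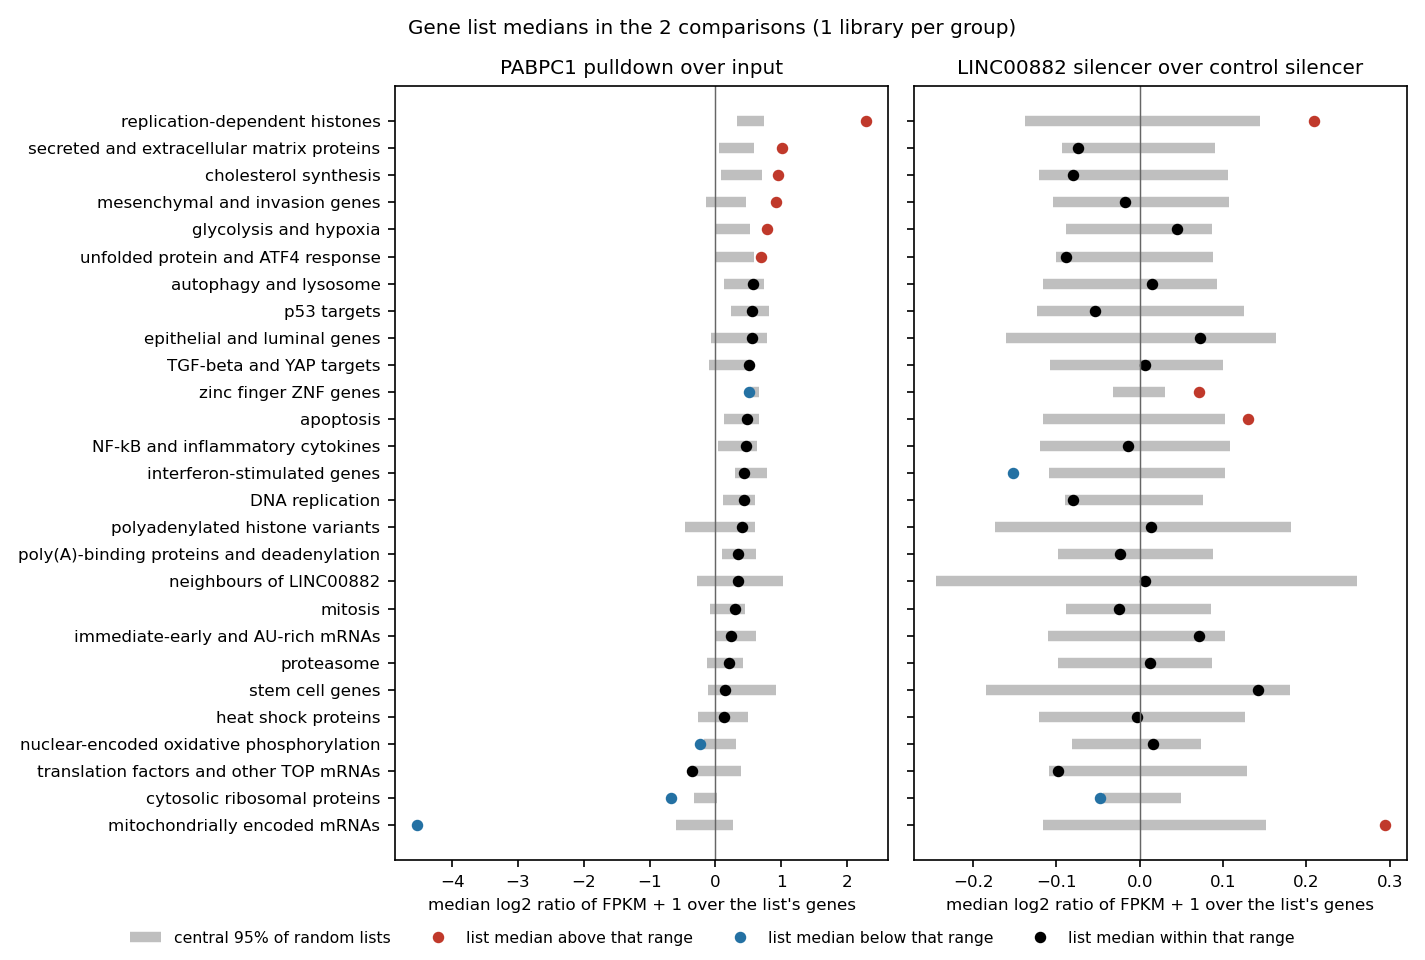
Median log2 ratio of FPKM + 1 of each gene list (points) and the central 95% of 10000 expression-matched random lists (grey bars) in the pulldown over input (left) and in si_LINC00882 over si_NC (right), on different horizontal scales. Of 27 lists, 10 lie outside the bars in the pulldown pair, with medians from -4.53 to 2.29, and 6 in the si pair, with medians from -0.15 to 0.29.

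Genes high in the pulldown and low after LINC00882 silencing were 39 of the 10230 genes compared in both pairs, where independent lists would share 21.7 and the central 95% of random lists held 14 to 30. The 10 with the largest changes in both included AHNAK (46.4 FPKM in the pulldown and 6.38 in input, 2.68), SPIN1, DAG1 (26.3 and 7.96, 1.61), FBXO34 and CALU, a calcium-binding protein of the secretory pathway. CALU stood at 58.9 in the pulldown and 11.1 in input (2.30), and at 34.9 in si_LINC00882 and 115 in si_NC (-1.70). The readthrough genes C7orf55-LUC7L2, PTGES3L-AARSD1 and C15orf38-AP3S2 were all listed at 0 in input and stood at 11.6, 9.52 and 6.58 in the pulldown. The rest of the 10 carry only clone names. With the control libraries exchanged, AHNAK (-1.24), CALU (-0.96) and PTGES3L-AARSD1 (-0.36) were lower in the pulldown, and SPIN1 (1.16), FBXO34 (1.37), CALU (1.56) and C15orf38-AP3S2 (0.67) higher in si_LINC00882. The other direction pairs were also more frequent than in independent lists. Genes higher in both numbered 29 (independent lists 16.1), genes lower in both 13 (2.504), and genes lower in the pulldown but higher in si_LINC00882 numbered 7 (1.86). Across all genes the log2 ratios of both comparisons correlated weakly, with Pearson's r of 0.022 and Spearman's rho of 0.040.

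The input and si_NC libraries, neither of which had a knockdown or a pulldown, differed by 2-fold or more at 2640 of 10511 genes (25.1%), with 625 higher and 2015 lower in input. Centred on the median log2 ratio, the numbers were 1054 and 1507. Mitochondrially encoded mRNAs were higher in input (median 2.11, 11 of 13 at 2-fold), as were replication-dependent histones (median 0.71, 9 of 24). Secreted and extracellular matrix genes (median -1.49, 20 of 31 at 2-fold lower), glycolysis and hypoxia genes (-0.75, 14 of 35) and mitosis genes (-0.70, 12 of 34) were lower in input. FPKM were normalised separately in each library, and the pairs differ in treatment and handling, so these differences are not a replicate spread.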

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

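The setting that leaves out overlapping and clone-named genes was chosen after seeing the data, and the others before. No paired analysis was possible because each group is 1 library and the labels give no replicate numbers. The planned ratio of LINC00882 has no value under any setting, as LINC00882 was not analysed here, and so the knockdown itself was not checked. The depth is unknown, so its effect on low genes could not be set apart. Below, counts of 2-fold genes are in the order higher and lower in si_LINC00882, higher and lower in the pulldown, different between input and si_NC, and high in the pulldown but low in si_LINC00882. As reported they were 90, 121, 2124, 257, 2640 and 39. Without a minimum, with protein-coding genes only, and rescaled without mitochondrial genes, all 6 counts stayed within 1.5 times these. With a pseudocount of 5 they were 23, 33, 623, 128, 964 and 12 (1.85 in independent lists), since a larger pseudocount shrinks the ratios of low genes. With 0.1 the counts that moved further were 160, 201, 3302 and, for the overlap, 70, where independent lists would share 54.4. Under the 1.5-fold rule they were 323, 390, 4561, 737, 5256 and 161, and the overlap then lay close to the 156.8 of independent lists. Under the 3-fold rule they were 18, 32, 639, 67, 888 and 10 (1.67 in independent lists). With a minimum of 5 FPKM the overlap was 24 against 15.4, and fewer genes were compared. Centring moved the pulldown counts to 943 and 708, with an overlap of 29 against 9.36. Without overlapping and clone-named genes, 57 genes were higher and 80 lower in si_LINC00882, and the overlap was 24 against 15.8 for independent lists, from fewer genes.

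Exchanging the control libraries also turned directions, and the cause was not tested here. Against input, 2005 genes were higher and 629 lower in si_LINC00882, and 12 lists lay outside the random lists in place of 6. Against si_NC, 774 genes were higher in the pulldown. Of the genes with a value there, 34 of 84 higher and 46 of 97 lower in si_LINC00882 were kept, as were 241 of 2093 higher and 60 of 236 lower in the pulldown. The medians of 16 of 27 lists changed sign for si_LINC00882 over input, and those of 8 of 27 for the pulldown over si_NC. Counting only lists outside the random lists with either control, those that changed sign over input were replication-dependent histones (-0.34), mitochondrially encoded mRNAs (-1.85), interferon-stimulated genes (0.079), apoptosis (-0.0032), oxidative phosphorylation (-0.44), secreted and matrix genes (1.43), mitosis (0.63), mesenchymal genes (0.39) and the unfolded protein response (0.66). For the pulldown they were oxidative phosphorylation (0.35), secreted and matrix genes (-0.25), glycolysis and hypoxia (-0.12), mitosis (-0.49), DNA replication (-0.11) and heat shock proteins (-0.35). These signs are relative to 0, while the median of all genes was 0.28 for si_LINC00882 over input and 0.16 for the pulldown over si_NC. Of the genes examined by name, 32 of 69 changed sign in si_LINC00882 over input and 17 of 65 in the pulldown over si_NC, PABPC1 among the latter (0.55). Those at 2-fold with either control were, over input, FBXO34 (1.37), SPIN1 (1.16), C15orf38-AP3S2 (0.67), MSRB3 (-0.17), TUBB3 (-0.0086), ZNF664 (-0.22), RRM2 (1.74), CALU (1.56), MT-ND5 (-1.09), MT-CYB (-2.07), MT-ND4 (-1.93), MT-ATP8 (-1.82), RPL39 (-1.18), PAIP2 (-1.45), CNOT10 (1.13) and ALCAM (1.62). Over si_NC they were BLOC1S5-TXNDC5 (-0.31), H3F3A (0.43), NDUFB4 (1.11), MMP14 (-0.057), COL6A1 (-0.91), PSAP (-0.24), P4HA2 (-0.49), PKM (-0.94), EIF4G1 (-0.76), CNOT10 (-0.27), PTGES3L-AARSD1 (-0.36), AHNAK (-1.24) and CALU (-0.96). With a pseudocount of 0.1 or centred, no named gene, and no list outside the random lists, changed sign.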

Other observations

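The tests on the 3 patterns of this part were chosen after the results were seen, and so were the genes that set the lysates apart; the use of si_NC as a control for list medians was chosen before the data were examined. Across the 11288 genes listed in all 4 libraries, 7 were at least 4-fold higher in both lysate libraries (input and pulldown) than in both transfected libraries, and 6 at least 4-fold lower. NPPB, the natriuretic peptide precursor, stood at 44.4 FPKM in input and 62.4 in the pulldown against 0.241 in si_NC and 1.2 in si_LINC00882. MMP1, an interstitial collagenase, stood at 30.6 and 35.8 against 3.51 and 2.75, and the cytokine IL1B at 9.23 and 18.7 against 1.48 and 1.28. MDK, RAB31 and the histone genes HIST1H4A and HIST1H4C were the others. ANGPTL4, an inhibitor of lipoprotein lipase, stood at 0.183 and 3.12 against 42.9 and 43.4, and fibronectin (FN1, which overlaps ATIC) at 6.09 and 14.5 against 85.7 and 81.4. PLEC, ABLIM3, RPL36A-HNRNPH2 and PGAM4 were the others, and the last pair overlap other listed genes. The tables were normalised separately, and treatment and handling differ between the pairs.

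Against si_NC, 23 NF-kB target and cytokine genes had a median log2 ratio of 0.95 in the pulldown, above all random lists, with 10 at 2-fold higher, whereas over input the list lay within them (0.47, percentile 79.33). The 25 cholesterol genes had a median of 0.80, with 8 at 2-fold higher, and so lay above the random lists with either control library. Mitosis genes had a median of -0.49 in the pulldown over si_NC, with 7 of 34 at 2-fold lower. Over input they lay within the random lists (0.29, percentile 77.76), and input itself was lower than si_NC (-0.70).

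Of 2093 genes higher in the pulldown than in input, 241 (11.5%) were also 2-fold higher than si_NC and 1255 (60.0%) were 2-fold lower in input than in si_NC, shares that are favoured by choosing the genes on their input values. The level in si_NC, which took no part in that choice, was nearer to the pulldown than to input for 78.1% of them (77.3% centred). Low values in the input library may account for many of these ratios, but the share alone does not decide it. No such share was computed for other genes. Across all genes si_NC correlated more closely with the pulldown (Pearson's r of 0.925) than with input (0.871). For replication-dependent histones (median 3.08 over si_NC, random lists -0.07 to 0.39) input alone is argued against. For mitochondrially encoded mRNAs it is argued against as the whole account, since the median remained at -2.53 over si_NC (random lists -0.33 to 0.43), but it was -4.53 over input and these mRNAs were themselves higher in input than in si_NC (2.11). No biological explanation of the low values in input was tested, and without an IgG library analysed here, binding to PABPC1 was not separated from recovery on the beads.

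Replication-dependent histone mRNAs were high in the pulldown although they mostly lack the poly(A) tail that PABPC1 binds. More cells in S phase would raise the DNA replication genes too. Input stands for the lysate of the pulldown, so S phase would not by itself give the ratios over input. The DNA replication median over input (percentile 72.04) therefore cannot test this. Over si_NC, which came from other cells, that median was at percentile 1.18 of random lists. The pulldown may itself shift these mRNAs, so that value does not decide it. Without a pulldown, the DNA replication median of input over si_NC was -0.54 (percentile 0.81). That argues against more cells in S phase in the lysate than in si_NC. A preference for short mRNAs stays open, since the oxidative phosphorylation list was below the random lists over input (-0.23, random lists -0.18 to 0.31) but above them over si_NC (0.35), while ribosomal proteins were low over both (-0.68 and -0.22). A difference in poly(A) selection between the libraries, which could lower histone mRNAs in the other 3, and binding of histone mRNAs by the pulled-down complexes also stay open and were not tested.

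Genes at 2-fold between si_LINC00882 and si_NC were also at 2-fold in the pulldown pair more often than matched genes, 46.3% (88 of 190) against 16.8 to 27.9%, in every pair of directions. That may reflect genes whose FPKM estimate is unstable between any libraries, but other accounts were not tested. A response to culture would not by itself give it, since input stands for the lysate of the pulldown. A known overlap with another listed gene was present in 23.7% of them (50 of 211), against 13.7 to 24.2% in random lists. Such overlap therefore does not cover most of them. Overlaps with genes not listed or not matched to RefSeq were not counted, so this share is a lower bound. In 7 of 7 opposite pairs such as ZBED6 with ZC3H11A the summed FPKM moved by less than 2-fold, but pairs picked for opposite change favour a steady sum, so reassigned fragments and real exchange cannot be told apart. The 39 genes high in the pulldown and low in si_LINC00882 decide nothing on a link between PABPC1 and LINC00882, since the ratio of their number to that of independent lists (21.7) was 1.795, and 1.796 to 5.19 in the other directions.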
